A study of Rattus norvegicus with 60 samples.

How the data were processed

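RNA of 5 brain regions from 12 adult rats was measured on 60 Affymetrix rat arrays. Per the labels' protocols, the rats were handled before the experiment, brains were dissected in the cold, and RNA of each rat was labelled and hybridized separately. Each region holds 6 arrays of the NP line and 6 of the congenic NP.P line. The deposited values are on the log2 scale, between 4.58 and 16.01, and the authors had summarized the probes to 31099 probe sets. Their method of background correction and normalization is not given in the sources used here. The 75th percentiles of the 60 arrays differ by up to 0.251 log2 units, so the arrays were not brought to equal quantiles. No 2 arrays were identical, and the highest correlation between 2 arrays was 0.996. Arrays give no read depth, and the number of animals limits the precision.

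The 57 array control probe sets were left out, which left 31042. Of these, 20826 carry 1 gene symbol in the probe table used, 436 carry several and 9780 are not listed in it. The gene identifiers of 20758 probe sets with 1 symbol were found in the reference gene table of the GRCr8 assembly, which gave chromosome and gene order only. The arrays' own build was not given, so no coordinates were used. Probe sets whose mean over all arrays lay at or above the 40th percentile (7.68) were kept, 18625 in all, of which 14030 carry 1 symbol, for 10378 genes. Probe sets with several symbols or none are given by ID, at most the 2 highest and 2 lowest of the mean over regions, apart from the 2 called for the interaction without 7 arrays.

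Analyses used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. For the line difference, the 5 log2 values of each animal were averaged and the 6 congenic animals were compared with the 6 NP animals in limma (linear model, empirical Bayes). Each region was compared in the same way on its 12 arrays. Tests were 2-sided with Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. The interaction of line and region was a limma F test with the animal as a fixed block. Region markers were found with limma against the mean of the other 4 regions, with the animal as a block, and called at least 2-fold higher. Chromosomes were compared with 2-sided Fisher's exact tests on genes of known chromosome, 10342 in all. Genes are not independent, so these tests describe the calls.

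Before the data were examined, 31 gene lists were fixed from general knowledge, and 29 of them had at least 5 measured genes. That of the neuropeptide Y system had 3 and that of blood 4, and neither was tested as a list. Lists were tested with limma's camera (preset correlation 0.01) on 1 probe set per gene, and again with an estimated correlation and with fry. Fry tests whether genes of a list move on balance in 1 direction, or, in its mixed form, in either. The chromosome 4 list (590 genes) had an adjusted p of 0.779 in camera and of 0.0478 in fry's mixed test on the mean over regions.

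Named genes were chosen by a rule fixed beforehand. It took the 12 highest and 12 lowest called genes with the same sign in all regions, called genes of the lists, and up to 10 called genes off chromosome 4. In each region it took the 3 highest and 3 lowest called genes and up to 3 off chromosome 4. It also took the 10 genes with the smallest interaction p, up to 4 genes per marker list, and Npy whatever its values. One further item of the rule is not reported here. Genes called only without the 7 arrays, genes called over a list or chromosome 4 alone, the numbered probe sets and the genes of the comparison of animal numbers were named after their values were seen.

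Arrays with the same number come from the same animal per the labels, so the numbers pair the regions and not the lines. Deviations from the group means correlated at a mean of 0.0139 over 120 pairs of arrays from 1 animal and at -0.00627 over 600 pairs from different animals. The consensus correlation of arrays from 1 animal was -0.0158. In the lines, animals 1 to 8 and 9 to 12 were fitted as a block in an alternative.

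Each array was correlated with the profile of each region, the median of the region's arrays minus the mean of the medians of all regions. For its labelled region the array itself was left out of the median. Arrays with a median correlation under 0.98 with their region, or a profile correlation under 0.5, were left out in an added alternative, 7 in all. The first limit was chosen after the data were seen and the second was added later, which brought in the array labelled amygdala NP 6. Other alternatives covered normalization, filter, prior, test, threshold, the animal as a random block and leaving out each animal or region. Alternatives to the pseudocount were not run, since the values were already logarithms. No labels were changed.

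The analysis was first tested on simulated data with known differences in 200 of 18625 probe sets. In the mean over regions, 92.2% of differences of 0.25 log2 units, 100% of those of 0.5 and 100% of those of 1 were recovered, with 11 false calls. For differences of 0.5, recovery was 66.1% in accumbens, 87.5% in amygdala, 88.1% in frontal cortex, 74.1% in hippocampus, 100% in striatum and 55.1% for the interaction. All 10 shifted lists were called by camera, with both correlations, and by fry, and of 10 unshifted lists fry called 1 and camera 0. The simulated probe sets were drawn independently of each other. This recovery thus does not show the power of the list tests for real lists, whose genes are correlated.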

Results

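Gene expression was measured in the brains of 12 adult rats on 60 oligonucleotide arrays. Each rat gave 5 regions: striatum, accumbens, amygdala, hippocampus and frontal cortex. In each region, 6 arrays came from NP rats, a line bred for low alcohol preference, and 6 from congenic NP.P rats. In NP.P rats, as known of the study and not from the labels, a chromosome 4 segment of the alcohol-preferring P line lies on the NP background. The series title gives the question, which genes are candidates for alcohol preference in these strains. Array medians lay between 8.23 and 8.35 log2 units, and the number of animals, 6 per line, limited the precision of each difference. A probe set, the array's unit for a transcript, was called at an adjusted p under 0.05. On 7 of the 60 arrays the profile stood apart from the other arrays of the labelled region, so each count of calls was also taken without them, an alternative chosen after the data were seen.

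Averaged over the 5 regions of each animal, transcripts of 14 named genes differed between the lines, and 13 of these genes lie on chromosome 4. Ppm1k, which encodes a mitochondrial phosphatase that activates the breakdown of branched-chain amino acids, fell by 1.22 ± 0.07 on the log2 scale in congenic rats (SE, 2.33-fold lower, adjusted p = 2.39e-07). Its mean log2 value was 9.07 ± 0.11 in NP and 7.85 ± 0.16 in congenic rats (SD, n = 6 each). Also lower were Creb5, a transcription factor of the family that binds cyclic AMP response elements (log2 difference -0.38 ± 0.05, adjusted p = 0.00177), Hnrnpa2b1, an RNA-binding protein (-0.30 ± 0.04, adjusted p = 0.00238), and Wdr91 (-0.19 ± 0.03, adjusted p = 0.0172). Higher were Magi1, a scaffold protein of cell junctions (0.47 ± 0.05, 1.39-fold, adjusted p = 0.00101), the zinc finger gene Zfp956 (0.39 ± 0.03, 1.31-fold, adjusted p = 3.54e-05) and Stmp1, which encodes a short mitochondrial protein (0.38 ± 0.05, adjusted p = 0.00295).

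Fam180a was higher by 0.33 ± 0.05 log2 units (adjusted p = 0.00450) and Dgki, a diacylglycerol kinase, by 0.25 ± 0.03 (adjusted p = 0.00247). Akr1b1, the aldose reductase, which reduces glucose and other aldehydes, was 1.18-fold higher (log2 0.23 ± 0.02, adjusted p = 2.09e-04). It was the only called gene of the 14 measured in the list of ethanol and aldehyde metabolism, and also the only one adjusted over the list alone. Pdia4, a protein disulfide isomerase of the endoplasmic reticulum (0.21, adjusted p = 0.0482), Repin1 (0.17, adjusted p = 0.0236) and Bpgm, the bisphosphoglycerate mutase (0.14, adjusted p = 0.0416), were higher as well. Sos1, an exchange factor that activates Ras, was the only called gene outside chromosome 4. It lies on chromosome 6 and was higher by 0.21 ± 0.03 (adjusted p = 0.00450). All 14 genes had the same sign of difference in the 5 regions, each by its called probe set. Of the other probe sets of these genes, that of Ppm1k (-0.31, adjusted p = 2.09e-04) and 1 of Magi1 (0.23, adjusted p = 0.00131) were also called. Hnrnpa2b1 was called by 1 of 4 probe sets, with the others at -0.13, -0.01 and 0.00, and Creb5 by 1 of 3, with the others at -0.18 and -0.04. The other probe set lay at -0.11 for Stmp1, opposite in sign, at 0.11 for Sos1 and at 0.12 for Bpgm, none called.

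The largest differences of all came from probe sets that carry no gene name in the table used. Probe set 1395714_at fell by 4.60 ± 0.06 on the log2 scale (adjusted p = 3.23e-16), from a mean of 12.02 ± 0.07 in NP to 7.42 ± 0.14 in congenic rats (SD, n = 6 each). Probe set 1391305_at fell by 3.00 ± 0.11 (adjusted p = 1.10e-09), to a congenic mean of 7.16. Both congenic means lie under the signal limit of the filter (7.68), which is a percentile and not a measured background. Whether these 2 differences, 24.3-fold and 8.00-fold, are lower bounds was not tested. A sequence variant of the lines under the probes was not excluded either. Probe sets 1378742_at and 1378125_at were higher by 0.73 ± 0.04 (adjusted p = 4.76e-08) and 0.35 ± 0.03 (adjusted p = 1.60e-05).

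**Figure D1:**
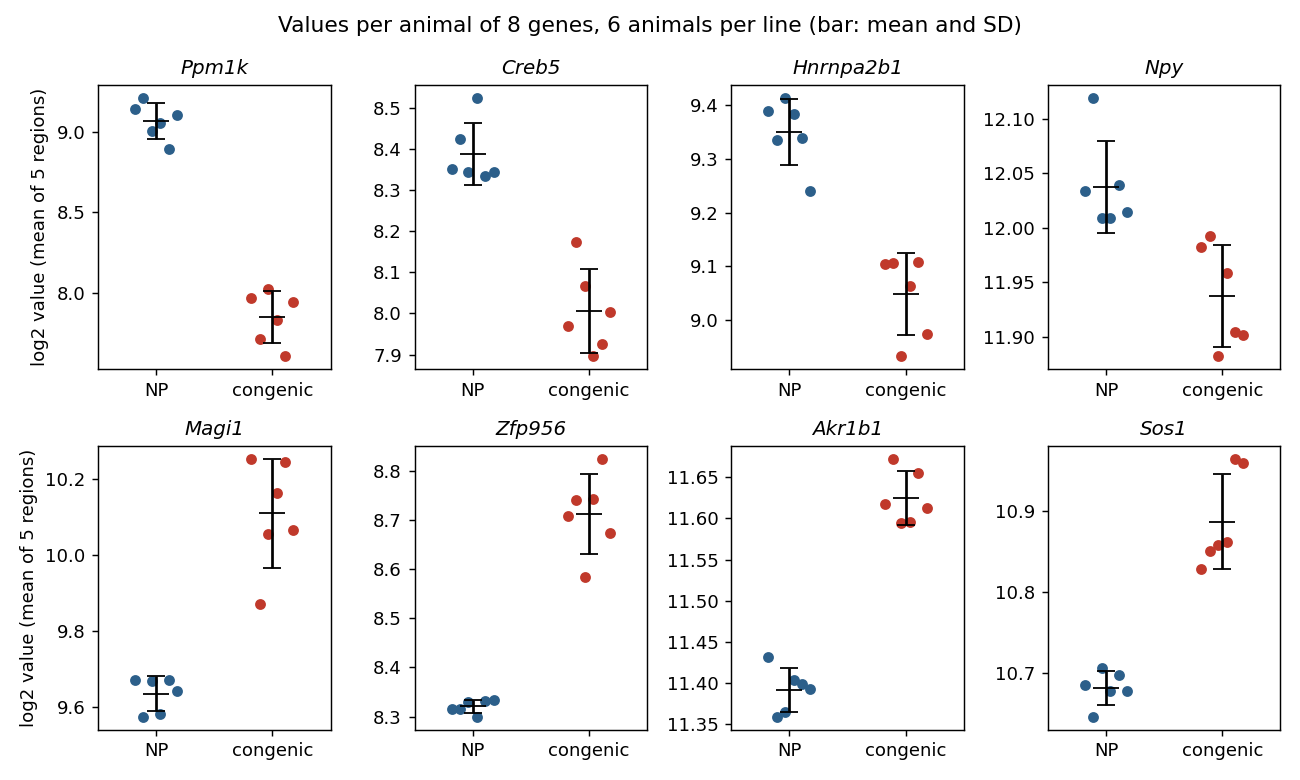
Log2 value of each animal, as the mean of its 5 regions, for 8 genes in NP (blue, 6 animals) and congenic rats (red, 6 animals), with the mean and SD of each line as bars and an axis range of its own in each panel. Ppm1k shows the widest separation, from a mean of 9.07 in NP to 7.85 in congenic rats, and Npy the narrowest, from 12.04 to 11.94.

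In total, limma called 23 of 18625 probe sets between the lines, 13 higher and 10 lower in congenic rats, and 992 had an unadjusted p under 0.05. Chance alone gives such a p to a share of 0.05 of the probe sets, so 992 is close to the number without any difference. The like counts given below have the same share by chance. Of the 23, 15 belong to chromosome 4 genes, 1 to Sos1 and 7 to no single gene. Filtering at the 60th percentile of signal left 11 calls, a test against a 1.2-fold difference left 4, and averaging without the hippocampus left 13. When single animals were left out in turn, 14 of the 18 named or numbered probe sets stayed called every time, whereas the calls of Bpgm, Pdia4, Repin1 and Wdr91 ended in 11, 10, 9 and 3 of the 12 leave-outs, with adjusted p up to 0.171.

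Npy, which encodes neuropeptide Y, is a chromosome 4 gene long discussed in these lines and was named before the data were examined, as were the gene lists, tests and thresholds. Its mean over regions was 12.04 ± 0.04 in NP and 11.94 ± 0.05 in congenic rats (SD, n = 6 each). The difference of -0.10 ± 0.03 did not pass over all probe sets (limma, adjusted p = 0.700) or over chromosome 4 alone (adjusted p = 0.0819). Taken alone, as a gene named in advance, Npy had an unadjusted p of 0.00325 (limma), and the animals of the lines did not overlap. By region, the Npy differences were 0.16 in accumbens, -0.25 in amygdala, -0.15 in frontal cortex, -0.19 in hippocampus and -0.07 in striatum, and none was called. The accumbens value changed sign without the 7 arrays, to -0.03, and without the accumbens array of animal 8 alone, to -0.00122. Without the 7 arrays the differences in amygdala and hippocampus shrank to -0.08 and -0.10. Npy1r (-0.04, adjusted p = 0.927) and Npy5r (-0.03, adjusted p = 0.953), which encode receptors of neuropeptide Y, were not called.

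Called genes were far more frequent on chromosome 4 than elsewhere. They were 13 of its 590 measured genes, against 1 of 9752 genes on other chromosomes (2-sided Fisher's exact test, p = 7.94e-16, adjusted over chromosomes p = 1.75e-14). Along the gene order of the GRCr8 rat assembly, 12 of the 13 lie in a run of 98 measured genes that starts at Akr1b1 and ends at Ppm1k, in the order Akr1b1, Bpgm, Wdr91, Stmp1, Fam180a, Dgki, Pdia4, Zfp956, Repin1, Hnrnpa2b1, Creb5 and Ppm1k. Magi1 stood apart from this run, with 133 measured genes in between. The run was bounded after the calls were seen, at the widest gap between called neighbours.

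Adjusted over the list alone, 27 of the 806 chromosome 4 probe sets were called, 15 higher and 12 lower, from 24 genes. In the run, 18 of the 98 genes were among these (18.4%), against 6 of the 492 other genes of the chromosome (1.22%), namely Adam22, Pot1, Tnpo3, Chchd3, Adamts9 and Magi1. Of the 18, 12 are the called genes by which the run was bounded. A higher share inside the run was thus fixed in advance and is no separate evidence of clustering. Snx10, a sorting nexin, and Hnrnpa2b1 are neighbours in the order of measured genes, at places 215 and 214, and Npy lies at place 210. Snx10 was higher by 0.47 ± 0.11 in the mean over regions (adjusted p = 0.0237 over chromosome 4 alone, 0.315 over all probe sets), and its other probe set lay at -0.16. Without the 7 arrays all 13 genes were called again, and Snx10 (0.59, adjusted p = 2.48e-06), Ggct (-0.26, adjusted p = 0.00919), Pot1 (-0.24, adjusted p = 0.0264) and Cntnap2 (-0.16, adjusted p = 0.00733), the gene of a neuronal adhesion protein, were called as well.

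**Figure D2:**
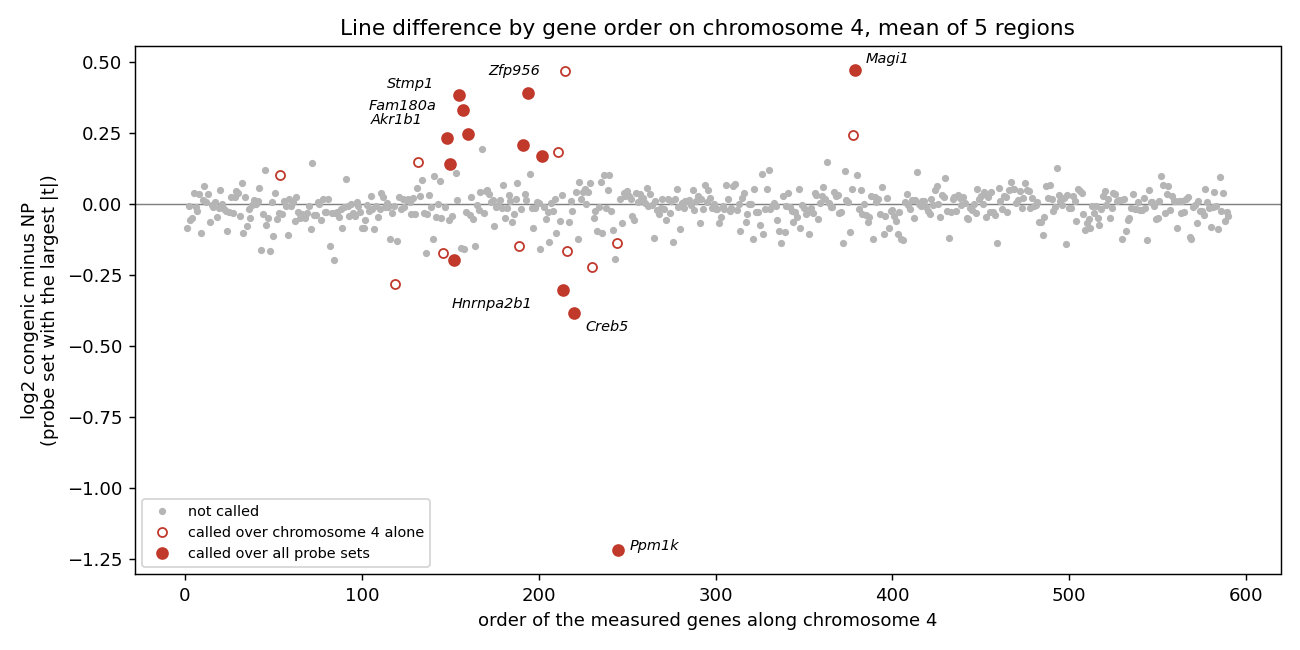
Log2 difference, congenic minus NP, of the 590 measured genes of chromosome 4 in their order along the chromosome, each by the probe set with the largest test statistic. Filled points are the 13 genes called over all probe sets, open points those called over chromosome 4 alone and grey points the others. 12 of the 13 filled points lie between places 148 and 245, and Ppm1k is lowest at -1.22.

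In the striatum, 12 probe sets differed between the lines, and every named one belongs to chromosome 4. Ppm1k fell by 1.04 ± 0.08 (2.05-fold, adjusted p = 2.17e-06) and Creb5 by 0.42 ± 0.05 (adjusted p = 0.00269). Snx10 was 1.55-fold higher (0.63 ± 0.08, adjusted p = 0.00298), Dgki 1.27-fold (0.34 ± 0.05, adjusted p = 0.00378) and Akr1b1 1.24-fold (0.31 ± 0.05, adjusted p = 0.0264). Of the 12, 6 were higher and 6 lower, 905 had an unadjusted p under 0.05, and 14 chromosome 4 probe sets were called adjusted over the list alone. A fit of all arrays with the animal as a random block called 6, a test against a 1.2-fold difference called 3, and the call of Akr1b1 ended in 8 of the 12 leave-outs of an animal (adjusted p up to 0.106).

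In the frontal cortex, 10 probe sets were called, 4 higher and 6 lower. Snx10 was higher by 0.66 ± 0.09 (1.58-fold, adjusted p = 0.00694) and Akr1b1 by 0.36 ± 0.05 (1.29-fold, adjusted p = 0.00568), while Ppm1k fell by 1.36 ± 0.14 (2.57-fold, adjusted p = 3.74e-04). Tpm3, a tropomyosin gene on chromosome 2, fell by 0.33 ± 0.06 in 1 of its 10 probe sets (adjusted p = 0.0474). Adjusted over the list alone, 11 chromosome 4 probe sets were called, and 1188 of all probe sets had an unadjusted p under 0.05. The Tpm3 call ended in 10 of the 12 leave-outs of an animal (adjusted p up to 0.169), with quantile normalization (adjusted p = 0.173) and with centring on the array medians (adjusted p = 0.107). The count was 6 with the animal as a random block or at the 60th percentile filter, and 4 against a 1.2-fold difference.

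In the amygdala, 6 probe sets were called, 3 higher and 3 lower, and the 3 with a gene name belong to Ppm1k, Stmp1 and Snx10. Ppm1k fell by 1.42 ± 0.06 (2.67-fold, adjusted p = 3.59e-08), Stmp1 was higher by 0.58 ± 0.08 (adjusted p = 0.0140) and Snx10 by 0.48 ± 0.07 (1.40-fold, adjusted p = 0.0243). The table held 1110 probe sets with an unadjusted p under 0.05, and 5 of chromosome 4 were called adjusted over the list alone, from 5 genes. Without the arrays labelled congenic 3 and NP 6, 18 probe sets were called. The named additions on chromosome 4 were Zfp956 (0.56, adjusted p = 0.00513) and Slc6a6, the taurine transporter (-0.62, adjusted p = 0.0314). Those on other chromosomes were Gabbr1, a subunit of the GABA-B receptor (-0.83), Egfr (-0.62), Vof16 (-0.58), Mef2a (-0.43) and Mindy2 (-0.31), with adjusted p of 0.0330 to 0.0352. Thus 5 of the 10 named genes called without these arrays lay off chromosome 4. The calls of Stmp1 and Snx10 ended in 4 and 8 of the 12 leave-outs (adjusted p up to 0.0640 and 0.102), and the count was 2 at the 60th percentile filter and 3 against a 1.2-fold difference.

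In the accumbens and in the hippocampus, the single probe set called was the unnamed 1395714_at. It fell by 4.65 ± 0.28 in accumbens (limma, adjusted p = 1.07e-05) and fell by 4.20 ± 0.36 in hippocampus (adjusted p = 5.99e-04). Ppm1k lay at -1.24 in accumbens (adjusted p = 0.946) and at -1.03 in hippocampus (adjusted p = 0.305), neither called. Adjusted over the list alone, Magi1 and Zfp956 were called in accumbens, and 4 probe sets of 3 chromosome 4 genes in hippocampus. An unadjusted p under 0.05 was found for 366 probe sets in accumbens and for 735 in hippocampus. Both regions hold arrays that stood apart. Without the arrays labelled NP 8 and congenic 9, 8 probe sets were called in accumbens, among them those of Ppm1k (-1.01, adjusted p = 1.87e-06), Magi1 (0.72, adjusted p = 4.16e-04), Snx10 (0.55, adjusted p = 0.00223) and Zfp956 (0.45, adjusted p = 0.0120). Without those labelled congenic 3, NP 8 and NP 11, 7 were called in hippocampus, among them Ppm1k (-1.24, adjusted p = 2.12e-04), Zfp956 (0.49, adjusted p = 0.0239) and Snx10 (0.48, adjusted p = 0.0297). The fit of all arrays with the animal as a random block called 9 in accumbens and 6 in hippocampus.

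Across the 5 regions, 14 probe sets were called in at least 1 region and 11 of them also in the mean over regions, whereas 12 were called in the mean alone. Probe set 1395714_at was called in all 5 regions. Without the 7 arrays, 5 probe sets were called in all 5 regions: those of Ppm1k and Snx10 and the unnamed 1395714_at, 1391305_at and 1378742_at.

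Whether the line difference itself varied between regions was tested with an interaction term. With all arrays, limma called 0 of 18625 probe sets, and 726 had an unadjusted p under 0.05. The 10 genes with the smallest p were Trip10, Sipa1l1, D430041D05Rikl, Rph3al, Exoc6b, Cplx2, Znf740, Strbp, Dok3 and Sdc3, each with an adjusted p of 0.866. Cplx2, a complexin that regulates the fusion of synaptic vesicles, showed the widest span of these. Its congenic minus NP differences were 0.45 in accumbens, -0.73 in amygdala, -0.50 in frontal cortex, -0.16 in hippocampus and 0.06 in striatum. Without the 7 arrays, 2 probe sets were called and 2006 had an unadjusted p under 0.05. They were 1395714_at, with differences of -4.89, -5.12, -4.85, -4.17 and -4.23 in accumbens, amygdala, frontal cortex, hippocampus and striatum, and 1394603_at, with 0.21, -0.51, -0.20, -0.13 and 0.10 (adjusted p = 0.0404 each). For 1395714_at the congenic means lay under the filter limit of 7.68 in each region with all arrays. At such low signal its differences may be compressed, so they do not by themselves show that the line effect varied.

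Each region carried its own set of higher transcripts. Against the mean of the other 4 regions, 117 probe sets were called at least 2-fold higher in striatum, 121 in frontal cortex, 85 in hippocampus, 47 in accumbens and 42 in amygdala, 412 in all. In the list of markers of medium spiny neurons, the projection neurons of the striatum, 17 of 18 genes were higher in striatum. Among them the dopamine receptor genes Drd2 and Drd1 were 6.77-fold (log2 2.76 ± 0.24, adjusted p = 5.54e-14) and 5.68-fold higher (2.50 ± 0.35, adjusted p = 1.68e-08), and Ppp1r1b, the phosphatase inhibitor DARPP-32, 5.67-fold. In accumbens 16 of the 18 were higher, among them Drd1 (1.97 ± 0.35, adjusted p = 3.82e-06), the tachykinin gene Tac1 (1.61 ± 0.33, adjusted p = 3.84e-05) and Rarb (1.57 ± 0.19, adjusted p = 2.23e-09). Leaving out the 7 arrays moved Drd1 there from 3.91-fold to 5.87-fold and Tac1 from 3.04-fold to 4.83-fold.

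In frontal cortex 9 of 15 markers of cortical excitatory neurons were higher, led by Lamp5 (1.47 ± 0.11, adjusted p = 1.76e-15), Fezf2 (1.16 ± 0.15, adjusted p = 7.43e-09) and Cux2 (1.10 ± 0.13, adjusted p = 8.15e-10), and Nr4a2 was lower (-1.05 ± 0.12, adjusted p = 1.04e-10). As a whole this list did not single out the region. Its mean log2 value, minus the centre of the 5 regions, had a median over arrays of 0.34 in frontal cortex and 0.31 in striatum. In hippocampus 8 of 10 hippocampal markers were higher, led by Prox1, a marker of dentate granule cells (1.88 ± 0.21, adjusted p = 2.54e-10), and Neurod1 (1.30 ± 0.15, adjusted p = 1.67e-09), while Kcnh3 was lower (-0.27 ± 0.03). Markers of the choroid plexus were also higher in hippocampus, 5 of 6, with Ttr, the gene of transthyretin, at 18.8-fold (4.24 ± 0.64, adjusted p = 3.07e-07) and Folr1 at 4.75-fold. Leaving out the 7 arrays raised these to 32.6-fold and 6.53-fold.

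In amygdala 2 of the 6 genes of the amygdala list were higher, Nts (0.42 ± 0.10, adjusted p = 5.08e-04) and Cyp26b1 (0.38 ± 0.14, adjusted p = 0.0177). As a whole this list did not mark the region, since its median over arrays was 0.06 in amygdala and 0.75 in accumbens. Without the 7 arrays Nts lay at 0.28 and Cyp26b1 at 0.56, and Cartpt was called lower (-0.43, adjusted p = 8.29e-07). Of the 10 thalamus and hypothalamus markers, 8 were higher in amygdala and Lef1 was lower (-0.20 ± 0.05). The neuropeptide genes Pmch (2.96 ± 0.44, adjusted p = 3.94e-07), Avp (2.20 ± 0.29, adjusted p = 2.10e-08) and Oxt (1.41 ± 0.23, adjusted p = 2.17e-06) led that list. Of 12 markers of meninges and fibroblasts, 9 were higher in accumbens, led by Ogn (1.08 ± 0.29, adjusted p = 0.00147), and 8 in amygdala, led by Fmod (0.96 ± 0.20, adjusted p = 9.63e-05). Without the 7 arrays the counts of probe sets at least 2-fold higher were 154 in hippocampus, 80 in amygdala and 76 in accumbens.

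**Figure D3:**
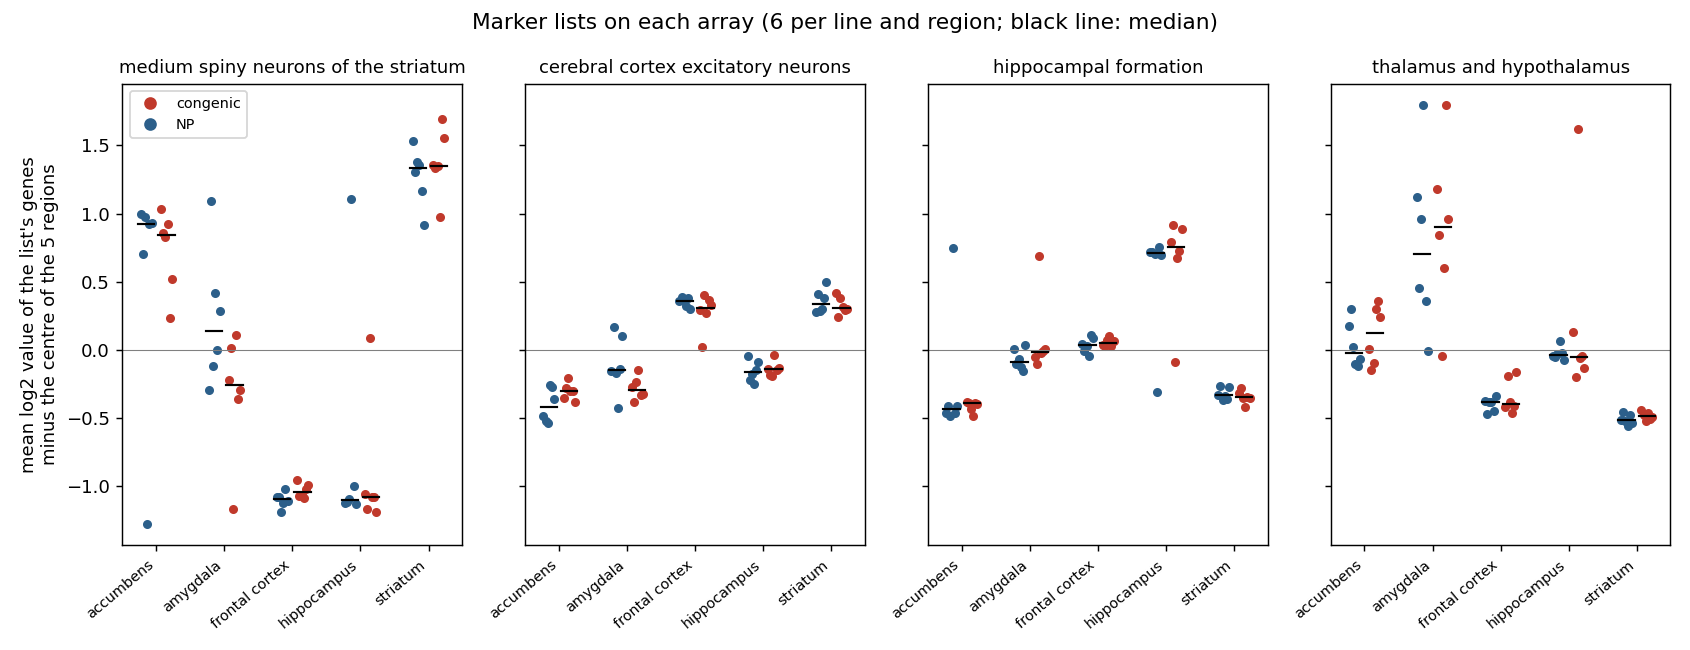
Mean log2 value of the genes of 4 marker lists on each array, minus the centre of the 5 regions, for NP (blue) and congenic (red) arrays, 6 per line and region, with a black line at each median. Medium spiny markers are highest in striatum and accumbens. The arrays labelled accumbens NP 8 and hippocampus NP 8 lie at -1.28 and 1.10 in that panel, away from the other arrays of those regions.

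On 4 arrays the profile lay nearest another region than the labelled one, taking each region's profile from its other arrays. The array labelled amygdala congenic 3 correlated at -0.07 with the amygdala profile and at 0.70 with that of hippocampus, and the one labelled hippocampus congenic 3 at -0.01 with hippocampus and 0.74 with amygdala. The array labelled accumbens NP 8 correlated at -0.04 with accumbens and 0.65 with hippocampus, and the one labelled hippocampus NP 8 at -0.21 with hippocampus and 0.39 with accumbens. These are correlations across probe sets, which are not independent replicates. Of the 3 other arrays left out, accumbens congenic 9 had a median correlation of 0.831 with the arrays of its region and hippocampus NP 11 one of 0.975. Amygdala NP 6 had a profile correlation of 0.24, and its medium spiny markers lay at 1.09.

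**Figure D4:**
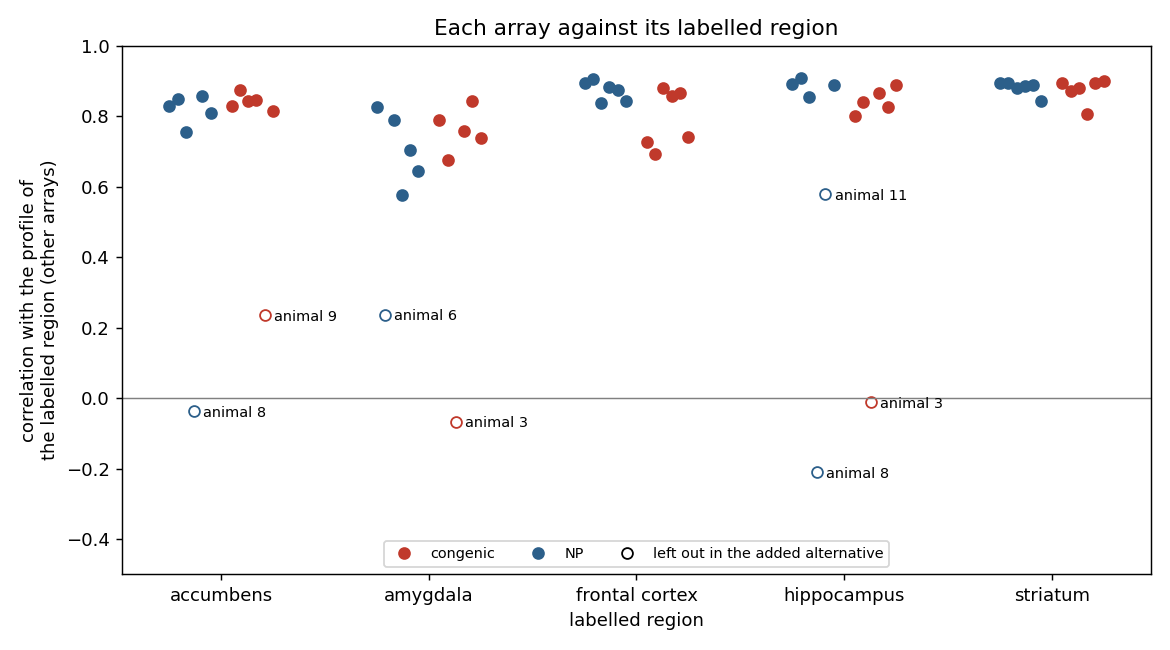
Correlation of each of the 60 arrays with the profile of the region it is labelled with, taken from the other arrays, by labelled region for NP (blue) and congenic (red) rats. Open points are the 7 arrays left out in the added alternative, between -0.21 and 0.58. The lowest of the 53 other arrays lies at 0.577.

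Among the 29 gene lists tested on the mean over regions, 6 passed camera with its preset correlation, and none passed with an estimated correlation or with fry's test for 1 direction. No member of the 6 lists was called on its own. Medium spiny markers were lower in congenic rats (18 genes, median -0.08, adjusted p = 1.21e-05; adjusted p = 0.687 with an estimated correlation), as were proteasome genes (34 genes, median -0.03, adjusted p = 8.94e-05; 0.687), ribosomal protein genes (41 genes, median -0.02, adjusted p = 0.00126; 0.687), immediate early genes (16 genes, median -0.08, adjusted p = 0.0415; 0.687) and genes of oxidative phosphorylation (72 genes, median -0.01, adjusted p = 0.0415; 0.760). Thalamus and hypothalamus markers were higher (10 genes, median 0.09, adjusted p = 0.0258; adjusted p = 0.687 with an estimated correlation). Without the 7 arrays the medium spiny median was -0.02 (adjusted p = 0.415) and the thalamus and hypothalamus median 0.05 (adjusted p = 0.632). The immediate early list did not pass either (median -0.06, adjusted p = 0.410), and of its members Arc was low in congenic animals 9 and 10 (9.32 and 9.59) and not in congenic animals 1 to 4 (10.15 to 10.39).

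The 23 other lists did not pass, and the lowest adjusted p among them was that of the heat shock proteins, 0.0887. Among the lists tied to alcohol, that of dopamine signalling (13 genes) had an adjusted p of 0.314, GABA signalling (15 genes) 0.225, glutamate receptors and transporters (26 genes) 0.366, serotonin signalling (6 genes) 0.297, opioid peptides and receptors (6 genes) 0.890 and the stress axis (9 genes) 0.761. Ethanol and aldehyde metabolism had 0.145 in camera and 1.88e-05 in fry's mixed test, which asks whether members change in either direction. Its only called member, also over the list alone, was Akr1b1 (0.23 ± 0.02), a chromosome 4 gene of the run. This gene may by itself carry the mixed result, and the list was not tested without it. Adjusted over the list alone, Gstp1 of the glutathione list and Aldh1l1 of the astrocyte list were called, and neither was called over all probe sets.

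Within regions, the lists that passed camera again passed only with the preset correlation. In amygdala, medium spiny markers had a median of -0.48 (adjusted p = 1.35e-11; adjusted p = 0.552 with an estimated correlation), and Pde10a was the 1 member called adjusted over the list alone. Without the arrays labelled congenic 3 and NP 6, whose medium spiny markers lay at -1.17 and 1.09, the median was -0.20 (adjusted p = 6.42e-08; adjusted p = 0.705 with an estimated correlation). GABA signalling, interneuron markers, proteasome and oxidative phosphorylation genes were lower as well (adjusted p = 0.00205, 0.0368, 9.77e-05 and 7.80e-04; 0.552, 0.633, 0.633 and 0.841 with an estimated correlation). Of these 4, only GABA signalling passed without the 2 arrays (adjusted p = 0.0177; interneuron 0.279, proteasome 0.0771, oxidative phosphorylation 0.124), and interneuron markers lay at -0.31 on the array labelled congenic 3 against 0.03 to 0.17 on the other congenic arrays. In frontal cortex, markers of the meninges (median -0.30, adjusted p = 3.75e-07; 0.663 with an estimated correlation) and of endothelium (median -0.08, adjusted p = 3.75e-07; 0.573) and ribosomal protein genes (median -0.02, adjusted p = 0.00442; 0.894) were lower. Single arrays weighed on the meningeal difference, with congenic 1 at -1.17 (other congenic arrays -0.28 to 0.39) and NP 12 at 1.01 (other NP arrays -0.17 to 0.38).

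In accumbens, oligodendrocyte markers (median -0.09, adjusted p = 0.0361), ribosomal protein genes (-0.04, adjusted p = 0.0361) and proteasome genes (-0.05, adjusted p = 0.0218) were lower and meningeal markers higher (0.22, adjusted p = 0.0494), each with an adjusted p of 0.960 with an estimated correlation. Without the 2 arrays that stood apart there, of these 4 lists only that of the proteasome passed with the preset correlation (adjusted p = 0.0139), and the meningeal median was -0.10 (adjusted p = 0.264). In hippocampus, oxidative phosphorylation genes were lower (median -0.05, adjusted p = 4.86e-05; adjusted p = 0.754 with an estimated correlation). Leaving out the 3 arrays that stood apart there gave -0.03 (adjusted p = 0.0107), and 6 lists in place of 1 passed with the preset correlation, 0 with an estimated one. In striatum, medium spiny markers were higher (median 0.10, adjusted p = 0.00210; adjusted p = 0.942 with an estimated correlation). Here 2 low arrays pulled the difference in opposite directions. NP 12 at 0.91 (other NP arrays 1.17 to 1.53) raised it, and congenic 4 at 0.98 (other congenic arrays 1.33 to 1.70) lowered it.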

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

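The tests of exchanged regions and of degraded RNA, and the interaction fit without the 7 arrays, were chosen only after the results were seen. Chance sets about 1 in 20 groups apart. The 10 groups of 6 arrays were looked at by 2 measures each, and 12 of these 20 looks, in 7 groups, set an array apart. Of 38 looks at 6 animals 1 did.

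On 4 arrays the values lay nearest the profile of another region than the one on the label. Among the 6 congenic amygdala arrays, that of animal 3 had a median correlation of 0.964 with the arrays of its region (nearest other 0.987) and a profile correlation of -0.0674 (0.676). Among the congenic hippocampus arrays, that of animal 3 had 0.971 (0.989) and -0.0119 (0.80). Among the NP arrays, that labelled accumbens 8 had 0.963 (0.988) and -0.0370 (0.755), and that labelled hippocampus 8 had a profile correlation of -0.211 (0.578).

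Degraded RNA was argued against by the array controls. In 4 of the 4 arrays both 5' control probe sets, of beta-actin and Gapdh, lay within 0.5 log2 units of the region's other arrays, the lowest at -0.47. An exchange of 2 regions of 1 animal stays open as a candidate explanation, since each of the 4 arrays had its highest profile correlation with the region that the other odd array of its animal is labelled as. For the array labelled hippocampus NP 8 this was narrow, 0.39 with accumbens against 0.38 with amygdala. The marker lists were further apart. On that array medium spiny markers lay at 1.10 and thalamus and hypothalamus markers at 0.06. The medians of the arrays were 0.89 and 0.01 in accumbens, and -0.06 and 0.90 in amygdala. No biological explanation was tested, and no label was changed.

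The array labelled accumbens congenic 9 had a median correlation of 0.831 with its region (nearest other 0.990) and a profile correlation of 0.235 (0.816). Its Gapdh controls lay at -6.31 at the 5' end and -1.71 at the 3' end, in log2 units against the region's other arrays, and its beta-actin controls at -4.35 and -3.88. The array labelled hippocampus NP 11 had 5' controls at -0.89 for beta-actin and -0.64 for Gapdh. Both arrays come from animals 9 to 12 and are among the 7 left out. The striatum array of congenic animal 4 had a median correlation of 0.988 (0.993) and a profile correlation of 0.807 (0.873), and that of NP animal 12 a profile correlation of 0.845 (0.882), both nearest their own region.

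Npy in NP animal 6 lay at 12.12, above the next NP animal at 12.04, as the mean over regions. The interaction of 1395714_at was called without the 7 arrays (limma, adjusted p = 0.0404), with differences from -5.12 in amygdala to -4.17 in hippocampus. With all arrays its congenic means lay under the filter limit of 7.68 in each region. At such low signal these differences may be compressed, so they do not by themselves show that the line effect varied. The interaction of 1394603_at was called as well (adjusted p = 0.0404), with differences from -0.51 in amygdala to 0.21 in accumbens. With all arrays both had an adjusted p of 0.998.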

How the results depend on the processing

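Leaving out the 7 arrays, and every alternative for chromosome 4 genes, was chosen after the data were seen. The count of 23 calls between the lines in the mean over regions was 11 at the 60th percentile filter, 4 against a 1.2-fold difference and 13 without the hippocampus. It was 24 with quantile normalization, 23 with median centring, 34 without a filter, 22 with a trended robust prior, 23 with the number set as a block and 34 with the animal as a random replicate block. Leaving out each animal gave 17 to 30. For probe sets of chromosome 4 genes adjusted over that chromosome alone (27) it gave 21 to 33, and for the 18 named or numbered probe sets 14 to 17. Fewer probe sets pass the fold test by construction. The stricter filter tests 12417 probe sets in place of 18625, which removes low signals but also lightens the adjustment, so its count could rise or fall. For the filter and the other changes the cause was not tested.

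Without the 7 arrays, calls were 8 in accumbens (with all arrays 1), 18 in amygdala (6) and 7 in hippocampus (1), and 2 for the interaction (0). Adjusted over chromosome 4 alone, 9 probe sets of its genes were called in accumbens (2). Region markers were 76 in accumbens, 80 in amygdala and 154 in hippocampus, gene lists in hippocampus 6 (1), and the Fisher adjusted p of chromosome 4 was 2.31e-04 in accumbens and 0.00407 in hippocampus (1 with all arrays). With the animal as a random replicate block, calls were 9 in accumbens, 6 in frontal cortex (10), 6 in hippocampus and 6 in striatum (12). It changed no other call count by over 1.5 times, the interaction count stayed 0 with it and with no replicate block, and region markers stayed at 412 with no replicate block. The number set block gave 2 in hippocampus. The 60th percentile filter gave 2 in amygdala and 6 in frontal cortex, and no filter gave 2 in hippocampus. The 1.2-fold test gave 3 in amygdala, 4 in frontal cortex and 3 in striatum. An adjusted p under 0.25 gave 21 in amygdala, 22 in frontal cortex and 2 in hippocampus. Adjustment over chromosome 4 alone gave 2 in accumbens and 4 in hippocampus.

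Region markers fell from 412 to 265 at the 60th percentile filter (22 in accumbens, 26 in amygdala, 77 in frontal cortex), were 132 in hippocampus without a filter, and were 28 at 4-fold (2 in accumbens, 2 in amygdala, 1 in frontal cortex, 7 in hippocampus, 16 in striatum). The Fisher adjusted p of chromosome 4 in amygdala was 1 at the 60th percentile filter and 1 with 1 probe set per gene, and in frontal cortex 0.0715 with 1 probe set per gene. The gene list counts were 0 with an estimated correlation and 0 with fry's test for 1 direction in the mean over regions and in each region. Quantile normalization gave 0 lists in accumbens and 3 in hippocampus, and the mean of all probe sets per gene gave 8 in amygdala, 2 in hippocampus and 2 in striatum.

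Npy in accumbens reversed to -0.0338 without the 7 arrays, and when animals were left out it lay between -0.00122 (without animal 8, reversed) and 0.205. Among the values of named genes and lists, 39 of 42 kept direction and side of the threshold with quantile normalization, 37 of 42 without the 7 arrays, 35 of 36 with median centring, 36 of 36 with the number set block and 368 of 432 when an animal was left out, where 63 ended a call. Array signal below the 40th percentile, taken as near background, was not tested in the main analysis, and alternatives to the pseudocount were not run.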

Other observations

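The comparison of animals 9 to 12 with animals 1 to 8, its tests, and the tests of strain variants, cell makeup and arrays that stood apart were chosen only after results were seen. The splits of the samples were planned, apart from those of the animal numbers.

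The labels number the rats 1 to 12, and both lines hold animals of either number range. With line as a block, 3 of the immediate early genes, Homer1, Klf2 and Dusp1, were lower in the mean over regions of animals 9 to 12 (4 animals) than in that of animals 1 to 8 (8 animals). Homer1 fell by 0.99 ± 0.16 on the log2 scale in 1 of its probe sets (1.98-fold, limma, adjusted p = 0.0165), whereas another of its probe sets lay at -0.03. Klf2, a transcription factor, fell by 0.53 ± 0.08 (adjusted p = 0.0151) and Dusp1, a phosphatase that turns off MAP kinases, by 0.52 ± 0.07 (adjusted p = 0.00877). Arc (-0.44, adjusted p = 0.0575), Junb (-0.25, adjusted p = 0.0523), Nr4a1 (-0.37, adjusted p = 0.0754), Fos (-0.25, adjusted p = 0.171) and Egr1 (-0.01, adjusted p = 0.953) did not pass, nor did Jun (0.11, adjusted p = 0.105) and Ptgs2 (0.15, adjusted p = 0.142), whose values were higher. Arc (-0.49, adjusted p = 0.0401) and Junb (-0.21, adjusted p = 0.0448) passed without the 7 arrays. The low Arc values were those of congenic animals 9 (9.32) and 10 (9.59), whereas NP animals 11 (10.02) and 12 (10.23) lay nearer to NP animals 5 to 8 (10.17 to 10.23). Nr4a1 lay at 9.99 and 10.32 in congenic animals 9 and 10, and at 10.74 and 10.91 in NP animals 11 and 12 (NP animals 5 to 8 at 10.80 to 10.91). Junb lay at 9.35 and 9.59 in these congenic and at 9.67 and 9.90 in these NP animals (NP animals 5 to 8 at 9.89 to 9.92). Klf2 was lower in all 4, at 8.14 to 8.64, against 8.86 to 9.24 in animals 1 to 8. The vessel markers Cldn5 (-0.17, adjusted p = 0.0447) and Flt1 (-0.19, adjusted p = 0.0334) were lower, while Kdr (-0.01), Pecam1 (0.03) and Ocln (0.05) of the same list were not called. Mex3b (0.35, adjusted p = 0.0165), Nexmif (0.27, adjusted p = 0.0165) and Etv1 (0.20, adjusted p = 0.00877) were higher. The calls of Flt1 (-0.12, adjusted p = 0.0922) and Etv1 (0.14, adjusted p = 0.0758) ended without the 7 arrays.

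In total, 396 probe sets were called between the number ranges, 182 higher and 214 lower in animals 9 to 12, and 4283 had an unadjusted p under 0.05. They name 255 genes, 13 of them on chromosome 4. With the preset correlation, 6 lists passed, all lower in animals 9 to 12. These were immediate early genes (16 genes, 2 called by the probe set tested in the list, 11 adjusted over the list alone, median -0.20, adjusted p = 2.71e-05), oligodendrocyte markers (median -0.11, adjusted p = 2.71e-05), medium spiny markers (median -0.09, adjusted p = 2.61e-04), endothelium (median -0.08, adjusted p = 3.99e-04), heat shock proteins (median -0.07, adjusted p = 0.00321) and dopamine signalling (median -0.03, adjusted p = 0.0224). None passed with fry's test for 1 direction, or with an estimated correlation (lowest adjusted p = 0.471 with an estimated correlation). In fry's mixed test, immediate early genes (adjusted p = 6.94e-04), endothelium (0.00462), heat shock proteins (0.00483) and medium spiny markers (0.0203) passed. Oligodendrocyte markers (0.215) and dopamine signalling (0.104) did not. Lists outside these 6 passed the mixed test too, among them that of the hippocampal formation (3.97e-06).

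The line is a block in the fit, so a line difference common to both number ranges would not give this pattern. The block does not remove a difference confined to the animals 9 to 12 of 1 line, and no interaction of line and number range was tested. The arrays that stood apart were argued against as the source of the pattern, since 501 probe sets were called without the 7 arrays (158 higher, 343 lower), 210 of them also with all arrays. A shared handling or array batch of animals 9 to 12 may account for it and cannot be told apart from a difference between the animals, since 0 columns of the labels give a batch or a day. Of 100 choices of 2 congenic and 2 NP animals, 1, the real one, gave as many calls (396), and the highest of the others gave 230. The comparison was chosen after results were seen, so this does not exclude chance.

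In the mean over regions, the calls between the lines lay mostly on chromosome 4. A different cell makeup or dissection in the lines was argued against as the whole source, since it would not favour 1 chromosome, and the Fisher adjusted p for chromosome 4 was 1.75e-14. The 7 arrays that stood apart were argued against too, since 13 of the 13 chromosome 4 genes were called again without them. A strain variant under the probes could not be excluded and may account for part of the calls. For the 24 genes called over chromosome 4 alone, 91.7% of their 24 other probe sets had the sign of the called one, with a median size of 0.251 of it. For the 13 genes called over all probe sets, 10 of 11 had that sign, with a median size of 0.159, and 2 were called. The bound on size was set after the share of signs was seen, and no probe-level values were used here. The inherited segment itself, as a difference of the lines, stays open and untested.

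In the mean over regions, 1 of 100 splits of the 12 animals, the real one, gave 23 calls or more, and the highest other gave 7. Chance is thus an unlikely source of this count. The same held for chromosome 4 alone (1 of 100, real 27, highest other 2), amygdala (1, real 6, highest other 2), frontal cortex (1, real 10, highest other 1) and striatum (1, real 12, highest other 1). In accumbens, 1 split gave as many as the real 1 (highest other 0), and in hippocampus 2 splits did (real 1, highest other 1). Counts this small do not by themselves exclude chance in these 2 regions. For probe sets called in 2 or more regions, 1 of 100 splits gave as many (real 9, highest other 0). For region markers, with regions relabelled within animals, 1 relabelling did (real 412, highest other 38). For the interaction, 100 of 100 splits gave as many as the real 0, and the highest other gave 7. For gene lists, 47 of 100 splits gave as many as the real 6, and the highest other gave 16, so chance cannot be excluded.

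Lists of 2 kinds of cells not tied to a region were also compared between the lines in the mean over regions. Microglia markers (14 genes, median -0.02) had an adjusted p of 0.376 and astrocyte markers (12 genes, median 0.01) one of 0.262.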
